A study of Mus musculus with 8 samples.

How the data were processed

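RNA was sequenced from mouse bone marrow-derived macrophages (macrophages grown from marrow with the growth factor M-CSF) of 2 genotypes. MYC f/f LysM cre cells, called KO here, carry a Myc gene that Cre recombinase made from the LysM (Lyz2) locus deletes in myeloid cells. LysM cre cells, called WT here, carry the same Cre and no floxed Myc. Cells of each genotype were left unstimulated in M-CSF (20 ng/ml) or were stimulated with LPS (bacterial lipopolysaccharide, 10 ng/ml) for 3 h. The titles label the unstimulated libraries 0 h and the LPS libraries 3 h, with no unstimulated library at 3 h. Changes after LPS may therefore include changes over 3 h of culture. Each of the 4 groups had 2 libraries, numbered replicate 1 and replicate 2, which gave 8 libraries in all. Per the labels the libraries were stranded and made from poly-A RNA. The authors processed reads with bcl2fastq 1.8.4, fastp, STAR 2.7.3a and edgeR on mouse genome mm10. The read counter and the gene annotation are not given in the sources used here.

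The deposited values are counts for 21571 genes, the same counts for 11599 genes kept by the authors' filter, and log2 CPM (counts scaled to a common library total) for those 11599 genes. For the genes held by both, the filtered counts were identical to the unfiltered counts. The deposited log2 CPM were checked and equal edgeR log2 CPM with TMM factors and a prior count of 0.25 on the filtered genes, with a largest difference of 7.1e-15. The rule behind the authors' filter was not identified. Gene positions are from a mouse GRCm38 (mm10) annotation, which held 21565 of the 21571 gene identifiers.

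Library totals ranged from 13211626 to 21970918 counts, so 3 counts, the floor used for a gene with no counts, correspond to 0.137 to 0.227 CPM per library. Folds against a group with 0 counts are lower bounds with 3 counts over that group. Ratios given against a group with 1 to 9 counts have an exact binomial 95% interval. These floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

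Before the data were examined, the comparisons, the tests, the gene lists, the rule for named genes and most alternatives were chosen. Unfiltered counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group (minimum count 10, minimum total 15), which left 13857 genes, and TMM factors were computed. A single quasi-likelihood model (robust) of the 4 groups used all 8 libraries, with 4 residual degrees of freedom. The 5 contrasts, tested with two-sided quasi-likelihood F tests, were LPS against rest in WT, LPS against rest in KO, KO against WT at rest, KO against WT after LPS, and the difference of the 2 LPS responses. A gene passed when its p, adjusted by Benjamini-Hochberg over the tested genes of that contrast, was under 0.05. Log2 fold changes are given with the standard error implied by the F statistic. CPM values are means of 2 libraries with SD. Within-replicate values are log2 CPM differences of 1 library against 1, with a prior count of 2 and no test.

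The titles carry one code on all replicate 1 libraries and another on all replicate 2 libraries, and the meaning of the codes is not stated. Whether the numbers pair the libraries was decided from the deviations of same-numbered libraries from their group means, correlated across genes for each pair of groups, with a threshold of 0.1 for all 6 pairs. The 6 correlations lay between 0.279 and 0.652 over all tested genes, and between 0.206 and 0.614 over autosomal genes, so the threshold was met. Genes are not independent replicates, so these correlations carry no p. The same model with the replicate number as a block (3 residual degrees of freedom), an alternative fixed beforehand, is therefore given beside the counts of genes, the counts of list members and the list calls that it changes. Camera p values are from the fit without the block unless stated.

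For gene groups, 32 lists with 711 genes were written beforehand from textbook pathways, the LPS stimulus, the deleted gene, glycolysis and Irf4, which the series title names, and markers of other marrow cells. Of these, 27 lists had at least 5 tested members. They were tested with limma 3.58.1 camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists of a contrast), and again with an estimated correlation, with fry, and with the block. For each list, members that passed are counted over all tested genes and adjusted over the list alone. Where a member had 0 counts in a group, the list median was also computed with that member at its bound.

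The named genes were Myc and Irf4 in each contrast, and the 6 largest and 6 smallest log2 fold changes among genes that passed with a mean of at least 10 CPM in the higher group and no overlap between the groups, leaving out genes with provisional symbols (Gm with a number, or ending in Rik or ps). Up to 3 passing members per list and direction were added, or the member with the smallest p where none passed. Hif1a, Hk2, Slc2a1, Ldha, Tnf, Il6, Il1b, Il12b, Nos2, Il10, Arg1 and Lyz2 were fixed for both KO against WT contrasts. The text names part of the genes this rule gave. The same rule was applied to the fit with the block after the data had been seen, which gave 25 further genes named for KO against WT at rest and 35 after LPS.

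Alternatives were DESeq2 1.42.0 size factors (RLE), no filter on low counts, the authors' filtered genes, the DESeq2 Wald test, limma-voom, limma-trend on the deposited log2 CPM, only the groups compared, an added absolute log2 fold change of at least 1, the block, and each library left out in turn. Leaving out both WT replicate 1 libraries, and every variation of the fit with the block, were added after seeing the data. No library was left out of the analysis. The test was run on simulated counts with the fitted means and replicate effects of the fit with the block. Dispersions were taken from their trend over genes, not from each gene. Among genes above a minimum mean CPM, 100 changed by 2-fold and 100 by 4-fold. For KO against WT after LPS, 1% of 2-fold and 74% of 4-fold changes were recovered without the block, against 67% and 100% with it. For the difference of the LPS responses, 0% and 0% were recovered without the block, against 20% and 94% with it. Among unchanged genes, 0 passed without the block and 6 with it in each of these contrasts. The simulation was built on the block and so favours it.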

Results

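Gene expression was measured in 8 RNA-seq libraries of mouse bone marrow-derived macrophages, 2 each of unstimulated WT, LPS-stimulated WT, unstimulated KO and LPS-stimulated KO cells. Total counts were 13975954 and 19116732 for WT at rest (replicates 1 and 2), 14237682 and 21970918 for WT after LPS, 15152101 and 17972597 for KO at rest, and 13211626 and 21925183 for KO after LPS. Between 17389 and 18785 genes were detected per library. The replicates of a group correlated across genes with r from 0.963 to 0.976 on the log2 CPM scale, where genes are not independent replicates. Their counts differed by more than counting error, with a chi-square per gene of 52.7 to 77.9. Xist, expressed from the inactive X chromosome, had 5652 to 8769 counts in the replicate 1 libraries and 0 to 1 in the replicate 2 libraries, although the labels call all samples female. Each group had n = 2, and log2 fold changes are given with their standard error (SE).

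Myc, the deleted gene (chromosome 15, 61985391 to 61990374, mm10), was lower in KO than in WT in each replicate and condition. At rest it was at 102 and 29.6 CPM in the WT libraries (replicates 1 and 2) and at 18.4 and 7.55 CPM in the KO libraries, which is 18.0% and 25.5% of WT. After LPS it was at 39.5 and 22.8 CPM in WT and at 11.3 and 6.95 CPM in KO, which is 28.7% and 30.5% of WT. Myc did not pass without the replicate block at rest (log2 fold change -2.35 ± 0.70, adjusted p = 0.521) or after LPS (-1.77 ± 0.70, adjusted p = 0.396). With the block it fell by 2.25 ± 0.27 on the log2 scale at rest (adjusted p = 0.0335) and by 1.76 ± 0.28 after LPS (adjusted p = 0.0362).

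**Figure D1:**
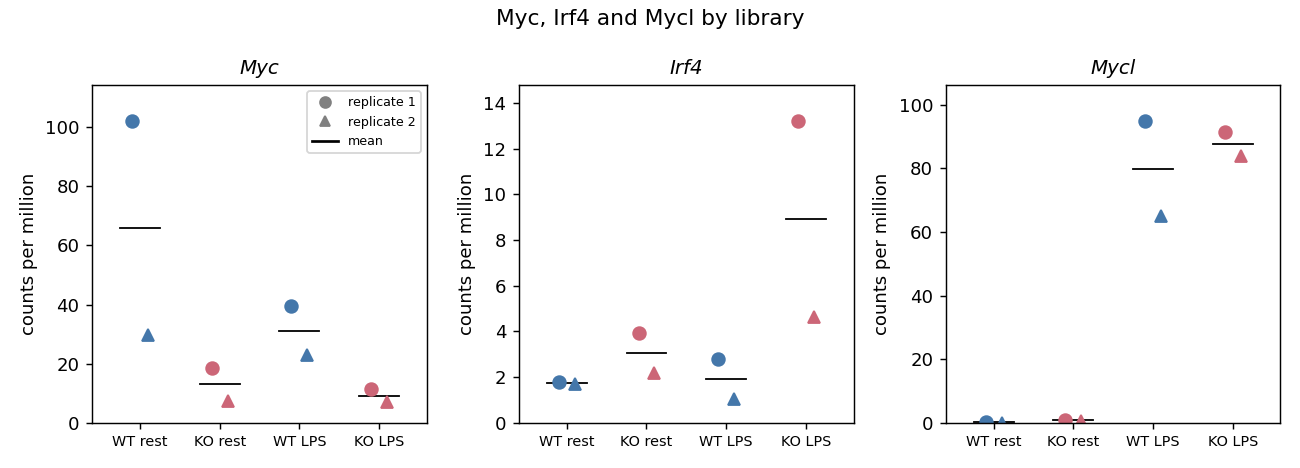
CPM of Myc, Irf4 and Mycl in each of the 8 libraries (linear axes from 0; circles, replicate 1; triangles, replicate 2; bars, mean of 2 libraries). Myc lies at 29.6 to 102 CPM in WT and 7.55 to 18.4 CPM in KO at rest, and Mycl has a mean of 0.139 CPM in WT at rest and 79.9 CPM in WT after LPS.

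LPS at 3 h was compared with rest, labelled 0 h, in WT cells to give their response. Cytokine genes were among the genes that rose. Il12b, which encodes the p40 subunit of IL-12 and IL-23 (chromosome 11, 44400063 to 44414033), rose from a mean of 0.161 CPM to 703 CPM (log2 fold change 12.07 ± 1.27, adjusted p = 0.00205). Csf2, which encodes GM-CSF, had 0 counts at rest and was at least 433-fold higher after LPS, Lif at least 246-fold and Lad1 at least 240-fold. Adamts4 and Il6 had 3 counts each at rest, and their ratios were 3980 (95% interval 1360 to 19300) and 2680 (918 to 13000). Among passing genes with established symbols, a mean of at least 10 CPM in the higher group and no overlap between the groups, the deepest falls were in Cnr2, the cannabinoid receptor 2 gene (log2 fold change -5.89 ± 0.48, adjusted p = 0.0007), Sox4, Dusp6, Zfp395, Zfp36l2 and Lpar6, at 24.1- to 59.4-fold (Sox4 had 6 counts after LPS, 95% interval 22.7 to 137). Of 13857 genes, 1223 rose and 1002 fell, and all 2225 had the same sign within both replicates. With the block 2385 rose and 2292 fell.

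Most members of the NF-kappaB and proinflammatory lists rose. Of 30 NF-kappaB targets and feedback regulators, 28 rose and 2 did not pass (28 adjusted over the list alone). Among them were Socs3 (667-fold), Dusp2 (120-fold) and Icam1 (34.8-fold). The camera adjusted p was 8.93e-30, and adjusted p = 0.35 with an estimated correlation. Of 33 proinflammatory cytokines and chemokines, 27 rose and 6 did not pass (29 rose adjusted over the list alone), including Cxcl1 (2010-fold), Cxcl2 (1040-fold) and Ccl3 (107-fold). The list median was 6.70 on the log2 scale, or 6.63 with the 3 members that had 0 counts at rest at their bounds (camera adjusted p = 1.54e-22, and adjusted p = 0.402 with an estimated correlation). Of 40 interferon-stimulated genes, 3 rose and 37 did not pass (2 adjusted over the list alone), with Gbp5 at 85.3-fold and Parp14 at 5.78-fold. Their median was 0.22 within replicate 1 and 2.42 within replicate 2 (camera adjusted p = 3.81e-05, and adjusted p = 0.868 with an estimated correlation). Among 8 interferon regulatory factors, Irf1 rose 12.5-fold, Irf8 fell 2.94-fold and Irf2 fell 1.66-fold, the same 3 adjusted over the list alone. Irf4 did not pass (log2 fold change 0.12 ± 0.67, adjusted p = 0.929, with -0.03 ± 0.40 in the fit with the block).

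Cell cycle and lipid synthesis genes that passed fell. Of 40 cell cycle and DNA replication genes, 11 fell and 29 did not pass (14 fell adjusted over the list alone), including Cdc6 (6.33-fold), Ccnd1 (3.25-fold) and Ccne1 (2.39-fold). For this list the camera adjusted p was 8.28e-05, and adjusted p = 0.69 with an estimated correlation. Of 29 cholesterol and fatty acid synthesis genes, 3 fell and 26 did not pass (2 adjusted over the list alone), with Elovl6 at 3.62-fold and Dhcr7 at 2.19-fold (camera adjusted p = 0.0127, and adjusted p = 0.868 with an estimated correlation). Antigen presentation had 2 of 22 members higher (2 adjusted over the list alone), with H2-Q7 at a log2 fold change of 3.91 ± 0.60 (camera adjusted p = 0.0129, and adjusted p = 0.81 with an estimated correlation). Dendritic cell markers had 2 of 12 members higher and 1 lower (5 and 1 adjusted over the list alone). Ccr7, with 2 counts at rest, had a ratio of 99.6 (95% interval 27.1 to 829), and Xcr1 rose 14.8-fold. That list's median was 1.16, or 0.82 with 1 member at its bound (camera adjusted p = 0.0283, and adjusted p = 0.81 with an estimated correlation). Among 16 neutrophil markers Lcn2 rose 29.2-fold and was the 1 that passed, also adjusted over the list alone (camera adjusted p = 0.0448, and adjusted p = 0.81 with an estimated correlation). Oxidative phosphorylation had 1 of 39 members higher (0 adjusted over the list alone; camera adjusted p = 0.0142, and adjusted p = 0.81 with an estimated correlation). Of 40 cytosolic ribosomal proteins 0 passed in edgeR without the block, 1 at an unadjusted p under 0.05 and 4 with the block, at a median of 0.21 (camera adjusted p = 0.00741, and adjusted p = 0.868 with an estimated correlation).

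Single genes stood out in lists that camera did not call. In glycolysis and glucose uptake (25 members, camera adjusted p = 0.719), Slc2a6 rose 14.3-fold and Eno2 12.6-fold while Bpgm fell 2.24-fold, and 4 rose and 1 fell adjusted over the list alone. In the tricarboxylic acid cycle list, Acod1, whose enzyme makes itaconate, rose 410-fold and was the 1 of 28 that passed (1 adjusted over the list alone). In hypoxia and HIF1 targets 3 of 22 rose (3 adjusted over the list alone), with Nos2 (7 counts at rest) at a ratio of 1370 (95% interval 665 to 3410) and Hif1a at 3.30-fold. In the MYC network (11 members) Mycl, with 5 counts at rest, rose with a ratio of 594 (95% interval 254 to 1830) and Mxd1 rose 2.75-fold, while Mnt fell 5.37-fold and Mxd4 2.63-fold (2 and 2 adjusted over the list alone). With the block Myc itself fell by 0.90 ± 0.26 on the log2 scale (adjusted p = 0.0419), against -1.08 ± 0.67 without it (adjusted p = 0.331), and without the WT_rest replicate 1 library its value was 0.07. Of 24 amino acid transport and ATF4 targets 5 rose (5 adjusted over the list alone), including Slc7a11 (101-fold), Slc7a2 (27.3-fold) and Nupr1 (10.7-fold). Heat shock genes Hspa1b and Hspa1a rose 34.8- and 15.1-fold, 2 of 21 (2 adjusted over the list alone). Of 24 macrophage identity markers 5 rose and 1 fell (5 and 2 adjusted over the list alone), with Cd14 at 7.95-fold and Spi1 at 2.58-fold higher. Of 22 alternative activation genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), with Kdm6b at 10.3-fold higher and Klf4 at 5.13-fold lower. Ribosome biogenesis (44 members) had Rrs1 higher (3.65-fold) and Polr3g lower (2.04-fold), polyamine genes (12) had Odc1 higher (2.01-fold) and Paox lower (3.04-fold), and lysosome and autophagy (34) had Sqstm1 higher (10.6-fold) and Uvrag lower (1.89-fold). Adjusted over the list alone these 3 lists had 1 and 0, 1 and 1, and 1 and 1 members higher and lower. Of 30 nucleotide and one-carbon synthesis genes 2 fell, with Ppat at 1.88-fold (0 adjusted over the list alone). With each of the 8 libraries left out in turn, Polr3g passed in 1 fit, Ppat in 1, Odc1 in 2, Irf2 in 2 and Paox in 3. With the block 1 of the 30 nucleotide and one-carbon synthesis genes rose and 9 fell (1 and 9 adjusted over the list alone). Camera then called that list (adjusted p = 0.0184, and adjusted p = 0.873 with an estimated correlation). Mylip rose 1.89-fold among 12 liver X receptor targets, Nfatc1 fell 2.45-fold among 9 osteoclast markers, and Ccr2 fell 3.23-fold among 10 monocyte and myeloid progenitor markers, and these 3 genes also passed adjusted over the list alone. Mitochondrially encoded genes had 0 of 9 passing in edgeR and 0 at an unadjusted p under 0.05. For alternative activation, liver X receptor targets, the MYC network and osteoclast markers the median was below 0 and the mean above 0, and camera placed the first 2 higher and the last 2 lower. With the block cell cycle genes fell in 20 cases, cholesterol and fatty acid genes in 5, and neutrophil markers rose in 7, proinflammatory genes in 28, antigen presentation in 3, oxidative phosphorylation in 2, interferon-stimulated genes in 2 and tricarboxylic acid cycle genes in 4. Members higher and lower with the block were 5 and 1 for dendritic cell markers, 7 and 3 for ATF4 targets, 4 and 1 for heat shock, 5 and 2 for hypoxia, 2 and 3 for glycolysis and 2 and 4 for the MYC network. They were 5 and 5 for alternative activation, 4 and 4 for lysosome, 5 and 3 for macrophage identity, 3 and 2 for ribosome biogenesis, 2 and 1 for polyamine, 1 and 1 for monocyte, 1 and 1 for osteoclast and 2 and 0 for liver X receptor genes. The count of 2225 was 1085 with only the WT libraries, 1427 without WT_rest replicate 1, 889 without WT_rest replicate 2, 785 without WT_LPS replicate 2, and 983 without both WT replicate 1 libraries.

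The response to LPS in KO cells was measured in the same way. Cytokine genes rose here too. Il12b rose from 0.227 to 1100 CPM (log2 fold change 12.14 ± 1.24, adjusted p = 0.00142) and Cxcl1 from 1.06 to 3220 CPM (11.60 ± 0.50, adjusted p = 0.000175). Csf2, with 1 count at rest, had a ratio of 4390 (95% interval 788 to 173000), Zfp811 was at least 219-fold higher, and Il6 and Adamts4 rose by 11.50 ± 1.75 and 11.45 ± 0.72 on the log2 scale. Dusp6, Zfp395, Cnr2, Lpar6, Rgs2 and Zfp36l2 fell 24.0- to 60.1-fold. In total 1680 genes rose and 1847 fell, and with the block 2857 rose and 3302 fell. The balance depended on the scaling: with RLE factors 1926 were higher and 1600 lower (3239 and 2915 with the block), and in DESeq2 2219 and 1779 (3181 and 2714 with the block). Of the genes that rose in WT 1187 also rose in KO, against 148 for independent sets, and of those that fell 956 also fell, against 134. The calls of both genotypes come from the same fit with a shared spread per gene, so independent sets are not a valid baseline. No gene passed in opposite directions, and the log2 fold changes of the 2 genotypes correlated across genes with r = 0.948, where genes are not independent replicates.

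NF-kappaB targets rose in KO in 28 of 30 cases (29 adjusted over the list alone), with Socs3 at 400-fold, Dusp2 at 162-fold and Icam1 at 60.2-fold (camera adjusted p = 1.99e-26, and adjusted p = 0.417 with an estimated correlation). Proinflammatory genes rose in 30 of 33 cases (32 adjusted over the list alone), with Cxcl2 at 1350-fold and Ccl3 at 145-fold. Their median was 8.06, or 6.97 with 3 members at their bounds (camera adjusted p = 1.4e-21, and adjusted p = 0.417 with an estimated correlation). Interferon-stimulated genes rose in 12 of 40 cases (13 adjusted over the list alone), led by Gbp5 at 282-fold (camera adjusted p = 7.84e-06, and adjusted p = 0.7 with an estimated correlation). Their median was 0.66 within replicate 1 and 2.66 within replicate 2. Cell cycle genes fell in 17 of 40 cases (18 adjusted over the list alone), with Cdc6 at 9.79-fold, Ccnd1 at 4.69-fold and Ccne1 at 3.26-fold (camera adjusted p = 2.46e-05, and adjusted p = 0.631 with an estimated correlation). With an estimated correlation the adjusted p was 0.631 for each of the next 6 lists. Antigen presentation had 4 of 22 members higher, Tap2 among them (2.15-fold; 2 adjusted over the list alone, camera adjusted p = 0.00104). Dendritic cell markers had 5 of 12 higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.0136), and neutrophil markers 1 of 16 higher (1 adjusted over the list alone, camera adjusted p = 0.00296). Heat shock genes rose in 3 of 21 cases (3 adjusted over the list alone, camera adjusted p = 0.021), Hspa1b by 51.5-fold and Hspa5, an endoplasmic reticulum chaperone gene, by 1.60-fold. With each library left out in turn, Tap2 and Hspa5 passed in 3 of 8 fits each. Oxidative phosphorylation had 1 of 39 higher (0 adjusted over the list alone, camera adjusted p = 0.021). Nucleotide genes fell in 6 of 30 cases (5 adjusted over the list alone, camera adjusted p = 0.0389), with Ppat at 3.05-fold and Umps at 2.53-fold. Ribosomal proteins had 0 of 40 passing in edgeR without the block, 8 at an unadjusted p under 0.05 and 12 with the block (camera adjusted p = 0.00063, and adjusted p = 0.709 with an estimated correlation).

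Glucose genes that rose in KO were Slc2a6 (23.5-fold), Eno2 (10.5-fold) and Slc2a1 (3.36-fold), while Bpgm fell 3.07-fold, 3 higher and 1 lower of 25 (3 and 1 adjusted over the list alone). Acod1 rose 608-fold, Hif1a 4.29-fold and Nos2, with 6 counts at rest, with a ratio of 1390 (95% interval 638 to 3790). Ccl17, with 1 count at rest, had a ratio of 1570 (95% interval 281 to 62100), and Kdm6b, a histone demethylase gene, rose 19.4-fold. Mycl rose 112-fold and Mxd1 3.37-fold, while Mnt fell 6.06-fold and Mxd4 2.86-fold. Irf1 rose 14.1-fold and Irf8 fell 3.37-fold. Irf4 did not pass (log2 fold change 1.53 ± 0.63, adjusted p = 0.12), and with the block it rose by 1.45 ± 0.34 (adjusted p = 0.0153). Myc did not pass in either fit (-0.51 ± 0.69, adjusted p = 0.635). Mertk fell 5.35-fold, Sat1 and Odc1 rose 2.07- and 2.46-fold, and the liver X receptor targets Mylip and Abca1 rose 2.93- and 2.78-fold. The median was below 0 and the mean above 0 for alternative activation, lysosome, MYC network and osteoclast genes, and ribosome biogenesis had a median of 0.03 and a mean of -0.05. With the block neutrophil markers rose in 11 cases, antigen presentation genes in 7, oxidative phosphorylation in 7, interferon-stimulated genes in 9, NF-kappaB targets in 27 and proinflammatory genes in 31, and cell cycle genes fell in 19. Members higher and lower with the block were 11 and 2 for heat shock, 8 and 1 for dendritic cell markers, 2 and 11 for nucleotide synthesis, 10 and 4 for ATF4 targets, 7 and 5 for alternative activation, 4 and 9 for ribosome biogenesis and 1 and 8 for cholesterol genes. They were 3 and 4 for glycolysis, 5 and 4 for hypoxia, 5 and 5 for lysosome and for macrophage identity, 2 and 4 for the MYC network, 3 and 2 for interferon regulatory factors and 4 and 1 for monocyte and for tricarboxylic acid cycle genes. They were 2 and 1 for osteoclast, 2 and 2 for polyamine and 3 and 0 for liver X receptor genes. The count of 3527 was 1497 without KO_rest replicate 1, 1259 without KO_rest replicate 2 and 1224 without KO_LPS replicate 2.

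KO was compared with WT at rest to show how unstimulated cells of the genotypes differed. With 2 libraries per group, an effect of the Myc loss cannot be told apart from other differences between the animals. Genes of protein synthesis lay lower in KO. Of 40 cytosolic ribosomal proteins, all 40 had a lower value in KO at a median log2 fold change of -0.79 (-0.83 within replicate 1 and -0.74 within replicate 2). With the replicate block 33 of them fell and 7 did not pass (40 adjusted over the list alone), among them Rpl12 (2.23-fold), Rpl32 (2.18-fold) and Rps2 (2.17-fold), each with adjusted p = 0.0256. Class II antigen presentation gene H2-Aa rose 5.29-fold and the monocyte chemokine receptor gene Ccr2 rose 3.35-fold with the block. Without the block 0 genes passed in edgeR, 0 in limma-voom and limma-trend and 120 in DESeq2, 988 had an unadjusted p under 0.05, and the lowest adjusted p was 0.213. With the block 36 genes rose and 131 fell (21.6% higher), against 311 and 354 (46.8%) in DESeq2 with the block, 158 and 250 (38.7%) with no filter and 41 and 137 (23%) in limma-voom. With the block 0 genes passed without either WT_rest, either WT_LPS or either KO_rest library, or without both WT replicate 1 libraries. Without KO_LPS replicate 1 and 2, 178 and 142 passed. The WT_LPS libraries are not part of this comparison, and each omission lowers the residual degrees of freedom. The KO_LPS omissions lower them as well and did not empty the calls, so this alone does not explain the losses. Whether the calls rested on single libraries is not decided, but they were not stable to these omissions. With 1 library left out and no block, log2 fold changes were -1.659 to -1.528 for Uck2 and -1.208 to -1.018 for Rps2. They varied more for Fn1, at 0.248 to 2.363.

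In the rest of this comparison, genes that rose or fell did so in edgeR with the block. None passed in edgeR or limma-voom without it, while 19 of the 50 gene results given here passed in DESeq2 without it. Among passing genes with established symbols, a mean of at least 10 CPM in the higher group and no overlap between the groups, the largest rises were in H2-Aa, Dgkg (4.76-fold), Fam83f (4.68-fold), Pvt1 (4.20-fold), Mmp12 (4.09-fold) and Gpr141 (3.66-fold). Pvt1, a long noncoding RNA gene just beyond Myc (chromosome 15, 62037986 to 62378096), rose by 2.07 ± 0.21 on the log2 scale (adjusted p = 0.0256). Under the same limits the deepest falls after Myc were in Ankrd13b (3.82-fold), Rcn1 (3.82-fold), Uck2 (3.03-fold), Gnl3 (2.92-fold) and Ptp4a3 (2.82-fold). Of 44 ribosome biogenesis genes 7 fell and 37 did not pass (43 fell adjusted over the list alone, 24 without the block), including Gnl3, Dkc1 (2.46-fold) and Nop16 (2.06-fold). The camera adjusted p without the block was 9.23e-31, and adjusted p = 0.227 with an estimated correlation. For ribosomal proteins the same values were 1.55e-49 and, with an estimated correlation, adjusted p = 0.163. Of 30 nucleotide and one-carbon synthesis genes 4 fell (13 adjusted over the list alone), including Shmt2 (2.38-fold), Impdh2 (1.89-fold) and Cad (1.78-fold), with camera adjusted p = 1.63e-08, and adjusted p = 0.131 with an estimated correlation. Of 24 amino acid transport and ATF4 targets 3 fell (9 adjusted over the list alone), namely Aldh18a1 (2.15-fold), Psat1 (1.72-fold) and Slc1a5 (log2 fold change -0.84 ± 0.11), with camera adjusted p = 1.91e-07, and adjusted p = 0.131 with an estimated correlation. Of 21 heat shock and chaperone genes Hspd1 (2.09-fold) and Cct5 (1.71-fold) fell (15 adjusted over the list alone), with camera adjusted p = 5.02e-12, and adjusted p = 0.131 with an estimated correlation. Srm, the spermidine synthase gene, fell 2.48-fold, 1 of 12 polyamine genes (2 adjusted over the list alone, camera adjusted p = 0.0512).

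Few genes of energy metabolism passed. Of 25 glycolysis and glucose uptake genes Slc16a1, the lactate transporter MCT1 gene, fell 2.51-fold and 24 did not pass (1 adjusted over the list alone). The list median was -0.23 (camera adjusted p = 0.0169, and adjusted p = 0.497 with an estimated correlation). Ldha, the lactate dehydrogenase gene, was at 721 ± 105 CPM in WT and 476 ± 36.9 CPM in KO (SD), and did not pass (log2 fold change -0.60 ± 0.35, adjusted p = 0.828). Hk2, Slc2a1 and Hif1a had log2 fold changes of 0.00 ± 0.50, 0.08 ± 0.38 and 0.01 ± 0.20 and did not pass. In the tricarboxylic acid cycle Idh3a fell 1.51-fold, 1 of 28 (3 adjusted over the list alone), with camera adjusted p = 6.86e-08, and adjusted p = 0.0836 with an estimated correlation. Oxidative phosphorylation had 0 of 39 passing in edgeR in either fit and 2 lower at an unadjusted p under 0.05, with camera adjusted p = 0.00185, and adjusted p = 0.323 with an estimated correlation. Scd1, a fatty acid desaturase gene, fell 16.7-fold, from 7.21 to 0.453 CPM, 1 of 29 cholesterol and fatty acid synthesis genes (3 adjusted over the list alone). That list's median was -0.12 within replicate 1 and -0.76 within replicate 2 (camera adjusted p = 6.82e-10, and adjusted p = 0.323 with an estimated correlation). Mycl, a Myc paralog with 5 counts in WT and 29 in KO, rose with a ratio of 5.93 (95% interval 2.27 to 19.6) and Myc fell, the 2 of 11 MYC network genes that passed (camera adjusted p = 0.0712). Mitochondrially encoded genes (camera adjusted p = 0.112), hypoxia and HIF1 targets (0.379) and liver X receptor targets (0.135) had 0 members passing in edgeR in either fit, and 1 each at an unadjusted p under 0.05.

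Monocyte and neutrophil markers lay higher. Of 10 monocyte and myeloid progenitor markers Ccr2 rose (5 adjusted over the list alone), at a list median of 1.43 (1.14 and 1.92 within replicates 1 and 2), with camera adjusted p = 1.95e-06, and adjusted p = 0.131 with an estimated correlation. Of 16 neutrophil markers Elane (5.98-fold) and Mmp8 (1.82-fold) rose (10 rose and 1 fell adjusted over the list alone), with camera adjusted p = 1.95e-06, and adjusted p = 0.278 with an estimated correlation. H2-Aa was the 1 of 22 antigen presentation genes that rose (6 adjusted over the list alone), with camera adjusted p = 0.00752, and adjusted p = 0.474 with an estimated correlation. That list's median was -0.28 within replicate 1 and 0.54 within replicate 2. Dendritic cell markers had 0 of 12 passing in edgeR in either fit, 2 higher at an unadjusted p under 0.05 and a median of 0.56 (1 adjusted over the list alone), with camera adjusted p = 0.0105, and adjusted p = 0.331 with an estimated correlation. Fn1, the fibronectin gene, rose 2.57-fold among 22 alternative activation genes (5 adjusted over the list alone), with camera adjusted p = 0.0493, and adjusted p = 0.323 with an estimated correlation. Of 34 lysosome and autophagy genes 1 rose (2 adjusted over the list alone), with camera adjusted p = 0.0402, and adjusted p = 0.36 with an estimated correlation. Lyz1 (2.29-fold) and Itgam (1.63-fold) rose among 24 macrophage identity markers (4 adjusted over the list alone, camera adjusted p = 0.336), whose median was -0.02 and mean 0.28. Osteoclast markers had 0 of 9 passing (1 at an unadjusted p under 0.05 in edgeR, 1 adjusted over the list alone, camera adjusted p = 0.246).

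Inflammatory genes did not pass at rest. NF-kappaB targets had a median of 0.18 with 0 of 30 passing in edgeR in either fit and 3 higher at an unadjusted p under 0.05 (camera adjusted p = 0.00875, and adjusted p = 0.497 with an estimated correlation). Proinflammatory genes had a median of 0.14, or 0 with 6 members at their bounds, and 4 of 33 higher at an unadjusted p under 0.05 (camera adjusted p = 0.218). Tnf, Il1b, Il12b, Nos2, Il10 and Arg1 had log2 fold changes of 0.41 ± 0.34, 1.81 ± 0.60, 0.57 ± 1.60, -0.20 ± 1.49, -0.17 ± 0.97 and -1.75 ± 0.96, and Il6, with 3 counts in WT, had a ratio of 1.70 (95% interval 0.331 to 11). Interferon-stimulated genes differed by replicate, with a median of -1.76 within replicate 1 and 0.49 within replicate 2 (camera adjusted p = 0.00185, and adjusted p = 0.597 with an estimated correlation). Irf7 had log2 fold changes of -3.30 and 0.87 within the replicates. Among 8 interferon regulatory factors 0 passed in edgeR in either fit and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.592), Irf4 at 0.81 ± 0.65 (adjusted p = 0.908), with a list median of 0.07 and a mean of -0.13. Cell cycle genes had a median of 0.33 within replicate 1 and 0.00 within replicate 2 and 1 of 40 higher at an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.0428, and adjusted p = 0.488 with an estimated correlation). Lyz2, the Cre locus (chromosome 10, 117277331 to 117282321), was at 13.6 CPM in WT and 8.99 CPM in KO and did not pass (-0.60 ± 0.28, adjusted p = 0.731).

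KO was compared with WT after LPS, the condition in which the series title places the effect of MYC on inflammatory genes. Proinflammatory genes and NF-kappaB targets lay higher in KO by their list medians. Csf2 was at 32.8 ± 7.34 CPM in WT and 113 ± 24.4 CPM in KO (SD, n = 2), and with the block it rose 3.45-fold (1.79 ± 0.17, adjusted p = 0.0231). Irf4 (chromosome 13, 30749226 to 30766976), which encodes interferon regulatory factor 4, was at 1.94 CPM in WT and 8.91 CPM in KO and rose 4.52-fold with the block (2.18 ± 0.37, adjusted p = 0.0365), against adjusted p = 0.299 without it (2.22 ± 0.66). Genes of ribosomes and nucleotide synthesis lay lower, as 37 of 40 ribosomal proteins and 28 of 44 ribosome biogenesis genes fell with the block. Without the block 0 genes passed in edgeR, limma-voom and limma-trend and 221 passed in DESeq2, 1666 had an unadjusted p under 0.05, and the lowest adjusted p was 0.154. With the block 237 rose and 366 fell, which is 39.3% higher, against 56.2% of 612 with RLE factors and 61.7% of 1367 in DESeq2. Calls with the block fell to 0 without either WT_LPS library, without KO_LPS replicate 2 or without both WT replicate 1 libraries, to 13 without KO_LPS replicate 1, and to 70 and 64 without KO_rest replicate 1 and 2.

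As at rest, verbs of change refer to edgeR with the block. None of these genes passed in edgeR or limma-voom without it, while 37 of the 67 gene results given here passed in DESeq2 without it. Of 33 proinflammatory cytokines and chemokines Csf2 and Il23a (3.81-fold) rose and 31 did not pass (11 adjusted over the list alone), at a median of 0.42 within replicate 1 and 0.78 within replicate 2. The camera adjusted p without the block was 6.37e-08, and adjusted p = 0.254 with an estimated correlation. Tnf had a mean of 6110 CPM in WT and 13300 CPM in KO, with log2 fold changes of 1.10 and 1.13 within the replicates, and was 2.17-fold higher without passing, with the block (adjusted p = 0.103) or without it (adjusted p = 0.299). Il6 (1.28 ± 0.30, adjusted p = 0.0791), Il12b (0.85 ± 0.27, adjusted p = 0.129) and Il1b (2.17-fold, adjusted p = 0.268) did not pass with the block either, and each was higher in KO within both replicates. Nos2 (-0.21 ± 0.25, adjusted p = 0.664), Il10 (-0.03 ± 0.61, adjusted p = 0.983) and Arg1 (-1.17 ± 0.63, adjusted p = 0.327) did not pass. Of 30 NF-kappaB targets 4 rose (7 adjusted over the list alone), including Icam1 (1.67-fold), Nfkb2 (1.49-fold) and Ikbke (1.46-fold), with camera adjusted p = 4.1e-07, and adjusted p = 0.254 with an estimated correlation. Of 8 interferon regulatory factors Irf4 and Irf5 (1.54-fold) rose (2 adjusted over the list alone, camera adjusted p = 0.101). Interferon-stimulated genes had 0 of 40 passing in edgeR in either fit, 0 at an unadjusted p under 0.05, and medians of -1.09 within replicate 1 and 0.61 within replicate 2 (camera adjusted p = 0.491). Their pooled median was 0.10 and mean 0.01, while camera placed them lower. Irf7 was at 693 CPM in WT_LPS replicate 1 and 72.8 CPM in KO_LPS replicate 1, and at 169 and 294 CPM in replicate 2.

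**Figure D2:**
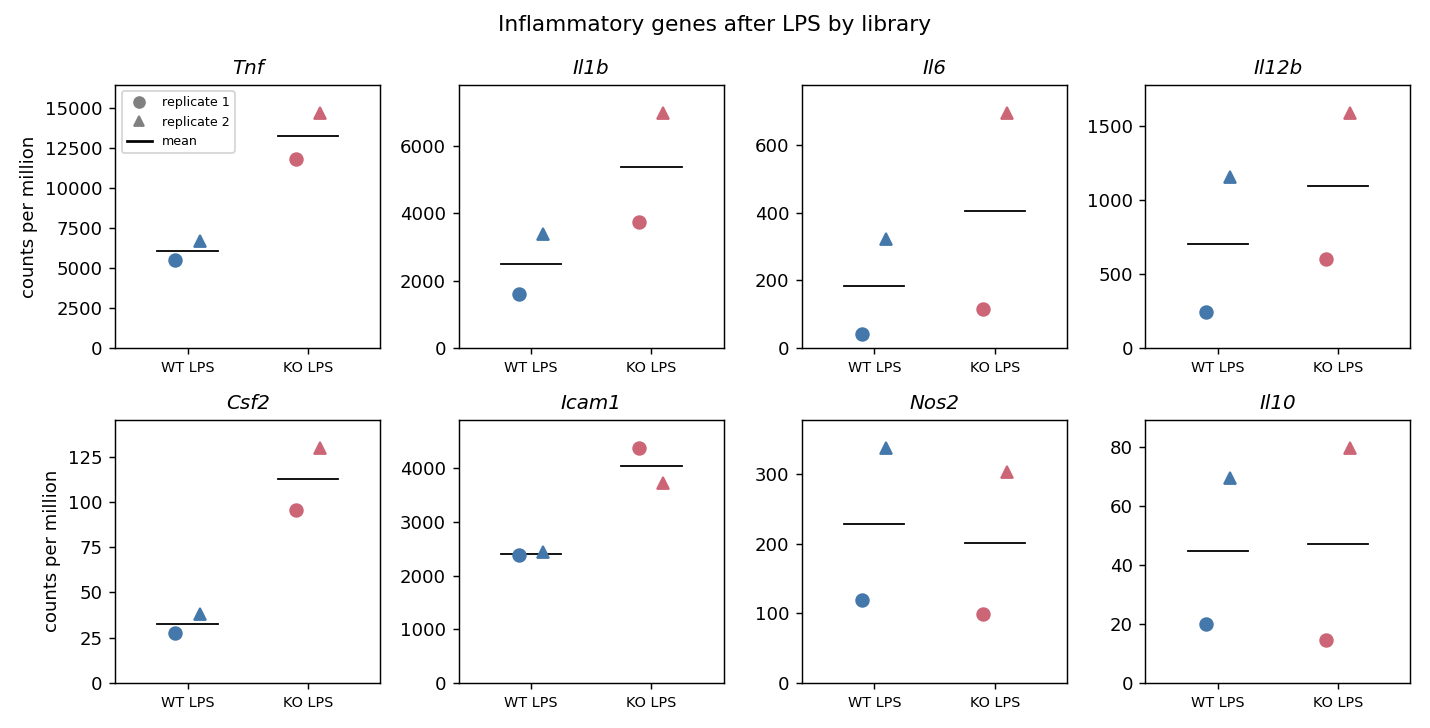
CPM of 8 inflammatory genes in the 4 LPS libraries (linear axes from 0; circles, replicate 1; triangles, replicate 2; bars, mean of 2 libraries). Tnf has means of 6110 CPM in WT and 13300 CPM in KO, and Csf2 means of 32.8 and 113 CPM.

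Biosynthesis lists repeated their lower position. Ribosomal proteins had a median of -0.73 (37 of 40 fell, 40 adjusted over the list alone), with Rpl12, Rps2 and Rpl32 2.23-, 2.10- and 2.01-fold lower (camera adjusted p = 1.72e-32, and adjusted p = 0.205 with an estimated correlation). With an estimated correlation, adjusted p = 0.205 also held for ribosome biogenesis, nucleotide synthesis and heat shock. In ribosome biogenesis 28 of 44 fell (41 adjusted over the list alone), including Dkc1 (3.94-fold), Nop16 (3.03-fold) and Nolc1 (2.43-fold), with camera adjusted p = 5.79e-26. In nucleotide and one-carbon synthesis 11 of 30 fell (20 adjusted over the list alone), including Shmt2 (2.49-fold), Cad (2.03-fold) and Atic (1.93-fold), with camera adjusted p = 5.3e-08. Among heat shock and chaperone genes 4 of 21 fell (11 adjusted over the list alone), including Hspd1 (2.17-fold), Fkbp4 (1.70-fold) and Cct5 (1.56-fold), with camera adjusted p = 3.34e-06. Of 24 ATF4 targets 5 fell (6 adjusted over the list alone), including Slc7a5 (3.54-fold), Aldh18a1 (2.96-fold), Slc1a5 (2.15-fold) and Psat1 (2.05-fold), with camera adjusted p = 0.00128, and adjusted p = 0.235 with an estimated correlation. Srm fell 4.24-fold, Uck2 3.71-fold, Nkain1 4.51-fold and Pter 4.27-fold. Srm was the 1 of 12 polyamine genes that passed (1 adjusted over the list alone, camera adjusted p = 0.368). In the tricarboxylic acid cycle Idh3a (1.58-fold) and Aco1 (1.45-fold) fell (8 adjusted over the list alone), with camera adjusted p = 4.14e-06, and adjusted p = 0.149 with an estimated correlation. Scd1 (13.2-fold) and Fasn (2.46-fold) fell among 29 lipid synthesis genes (3 adjusted over the list alone), at medians of -0.05 and -0.96 within replicates 1 and 2 (camera adjusted p = 4.21e-06, and adjusted p = 0.388 with an estimated correlation). Oxidative phosphorylation had 0 of 39 passing in edgeR in either fit and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0137, and adjusted p = 0.388 with an estimated correlation).

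Glycolysis genes were not called as a list after LPS (camera adjusted p = 0.218), at a median of -0.24. Slc16a1 fell 2.53-fold and 24 of 25 did not pass (1 adjusted over the list alone). Hk2 (log2 fold change 0.08 ± 0.50), Slc2a1 (0.46 ± 0.38), Ldha (-0.52 ± 0.35) and Hif1a (0.38 ± 0.20) did not pass in either fit, and Hk2 was -0.84 within replicate 1 and 0.53 within replicate 2. Hypoxia and HIF1 targets had 0 of 22 passing in edgeR in either fit and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.867), with a median of -0.02 that camera placed higher. In the MYC network Myc was the 1 of 11 that fell (1 adjusted over the list alone, camera adjusted p = 0.109). Mitochondrially encoded genes had 0 of 9 passing in edgeR in either fit and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.491), and cell cycle genes had 0 of 40 passing in edgeR in either fit and 1 higher at an unadjusted p under 0.05 (camera adjusted p = 0.438).

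**Figure D3:**
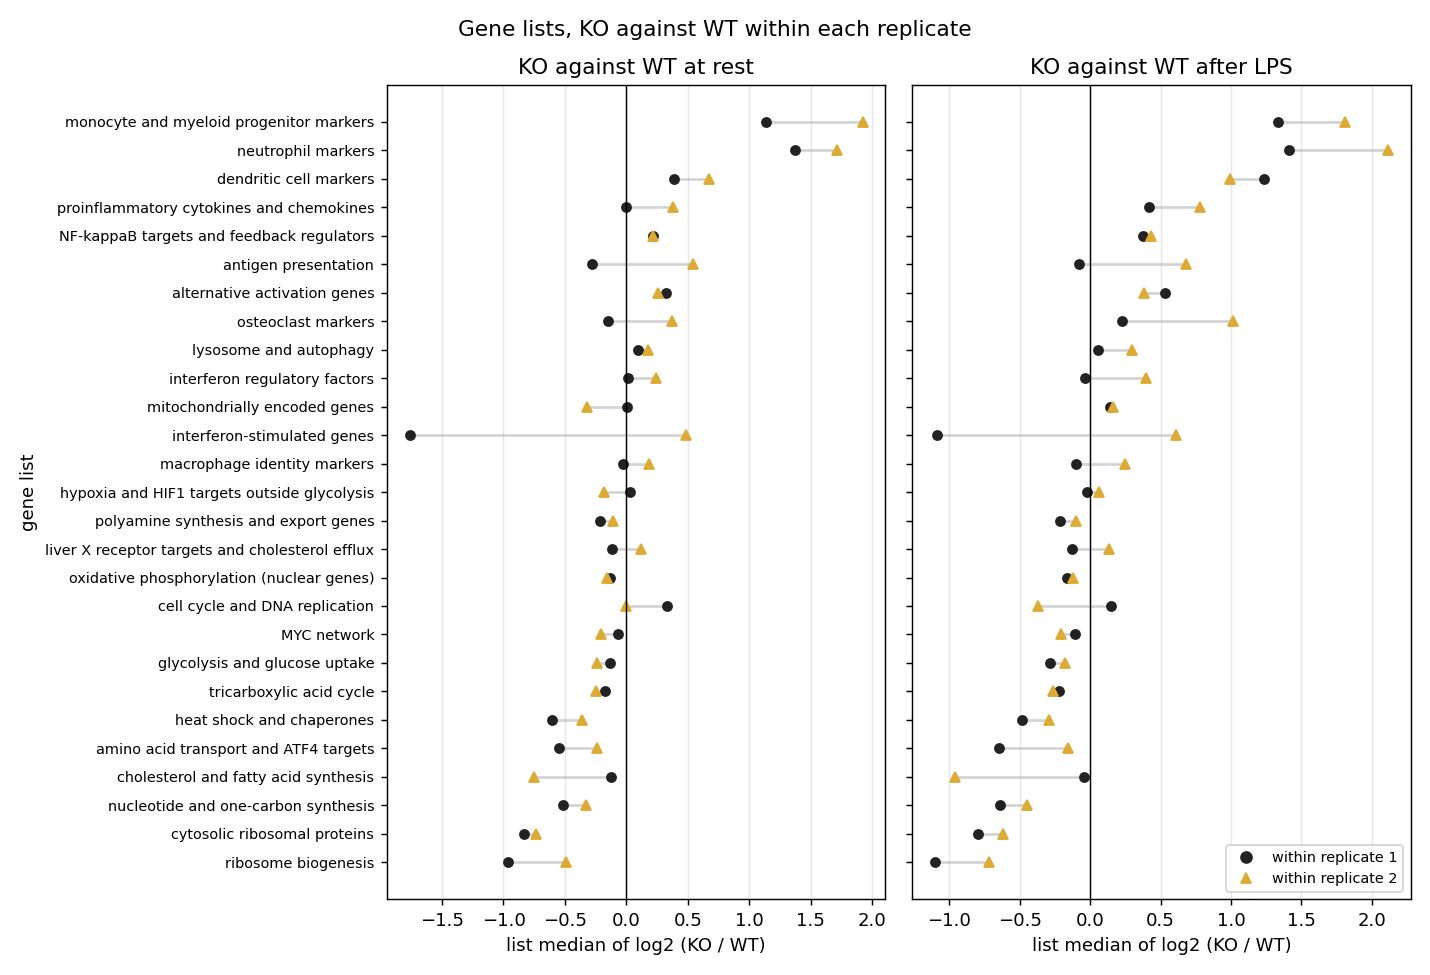
Median over each gene list of the log2 ratio of KO to WT CPM within replicate 1 (circles) and replicate 2 (triangles), at rest (left) and after LPS (right), for the 27 tested lists in the order of their medians after LPS. Cytosolic ribosomal proteins lie at -0.83 and -0.74 at rest, and interferon-stimulated genes at -1.76 and 0.49.

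Markers of neutrophils and monocytes lay higher in KO after LPS as well by their lists, and so did some antigen presentation genes. H2-Aa (6.64-fold), Ciita (5.93-fold) and H2-Eb1 (5.49-fold) were among 4 of 22 antigen presentation genes that rose (7 adjusted over the list alone), with camera adjusted p = 8.67e-06, and adjusted p = 0.254 with an estimated correlation. That list's median was -0.08 within replicate 1 and 0.68 within replicate 2. With an estimated correlation the adjusted p was 0.205 for neutrophil, dendritic cell, alternative activation and lysosome lists. Of 16 neutrophil markers 7 rose (13 adjusted over the list alone), including S100a8 (4.29-fold), Mpo (3.83-fold) and Mmp8 (2.22-fold), with camera adjusted p = 7.86e-09. Of 10 monocyte and myeloid progenitor markers Cd34 (5.99-fold) and Ccr2 (3.10-fold) rose (8 adjusted over the list alone), with camera adjusted p = 5.04e-07, and adjusted p = 0.15 with an estimated correlation. Ccr7 rose 2.55-fold among 12 dendritic cell markers (6 adjusted over the list alone, camera adjusted p = 6.04e-06). Of 22 alternative activation genes 5 rose (7 adjusted over the list alone), including Irf4, Fn1 (2.74-fold) and Kdm6b (2.29-fold), with camera adjusted p = 0.000867, and Ccl17 rose 7.61-fold. Of 34 lysosome genes 2 rose, with Hexa at 1.56-fold (4 adjusted over the list alone, camera adjusted p = 0.0006). Of 24 macrophage identity markers 4 rose (4 adjusted over the list alone, camera adjusted p = 0.0897), including Timd4 (8.47-fold), Lyz1 (2.45-fold) and Itgam (1.86-fold), at a median of -0.02 and a mean of 0.25. Itgb3 rose 2.56-fold, the 1 of 9 osteoclast markers (2 adjusted over the list alone, camera adjusted p = 0.0844). With the block camera called the osteoclast list (adjusted p = 0.0358, and adjusted p = 0.295 with an estimated correlation). Mylip rose 1.89-fold, the 1 of 12 liver X receptor targets (2 adjusted over the list alone, camera adjusted p = 0.911), a list with a median of -0.10 that camera placed higher. Pvt1 rose 7.83-fold and Gpr141 5.14-fold. Lyz2 did not pass (-0.55 ± 0.27, adjusted p = 0.497). Of B cell, erythroid and megakaryocyte, fibroblast and endothelial, mast cell and basophil, and T and NK cell markers, 3, 3, 4, 2 and 1 were detected well enough to test, and among them Ppbp, a platelet chemokine gene, rose 3.38-fold after LPS. With the block 30 genes rose and 125 fell both at rest and after LPS, against 0.616 and 3.46 for independent sets. Whether cells at rest and after LPS came from the same animals is not stated, so these sets may share material. Both sets also come from the same fit with a shared spread per gene, so independent sets are not a valid baseline.

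The difference of the LPS responses asked whether KO cells responded more or less to LPS than WT cells. Icam1 rose 60.2-fold in KO and 34.8-fold in WT, but the difference, 0.79 ± 0.26 on the log2 scale, did not pass (adjusted p = 1). Irf4 (1.41 ± 0.92), Myc (0.57 ± 0.96), Sat1 (0.57 ± 0.22), Mylip (0.64 ± 0.21), Bysl (-0.78 ± 0.38) and Mycl (-2.37 ± 0.56) did not pass either. In edgeR 0 genes passed without the block (84 at an unadjusted p under 0.05) and 0 with it (361), and 0 passed in DESeq2, limma-voom and limma-trend. Both counts are under a share of 0.05 of the 13857 tested genes, the share expected with no true difference. The tests were thus conservative here, and 0 calls do not show equal responses. Neither fit has a term for animals that cells at rest and after LPS may share. In simulated data this contrast recovered 0% of 4-fold changes without the block and 94% with it. The simulation favours the block, took dispersions from their trend over genes and changed only genes above a minimum mean CPM. The 94% therefore does not show how many 4-fold differences the real data would have revealed. Camera called 10 lists, among them proinflammatory cytokines and chemokines, whose median difference was 0.42 (0.46 and 0.42 within the replicates, adjusted p = 0.00102), and NF-kappaB targets, with 0.20 (0.15 and 0.20, adjusted p = 0.00363). With an estimated correlation the adjusted p was 0.774 for both, and 0 of the 10 lists passed. Fry called 0 lists, without the block or with it. With the block camera also called ribosome biogenesis (adjusted p = 0.0285), neutrophil markers (0.0384) and interferon regulatory factors (0.046), and with an estimated correlation their adjusted p was 0.825, 0.721 and 0.721.

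**Figure D4:**
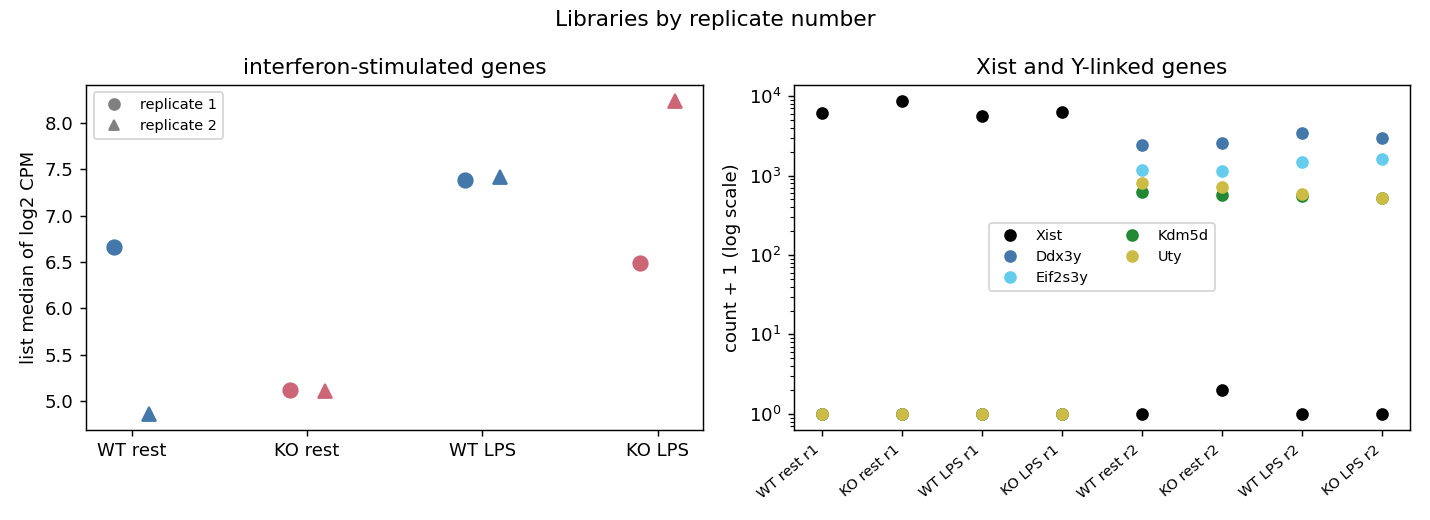
Left, median log2 CPM of 40 interferon-stimulated genes in each library (circles, replicate 1; triangles, replicate 2). Right, counts plus 1 on a log axis of Xist and 4 Y-linked genes in each library, with Xist at 5652 to 8769 counts in replicate 1 and 0 to 1 in replicate 2.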

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

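The difference of the LPS responses was among the comparisons chosen beforehand, while all tests of explanations in this part were chosen after the result was seen. Camera with the preset correlation called 10 gene lists for the difference between the LPS responses of KO and WT cells. Positive medians mark lists that responded more, or fell less, in KO. Fry called 0 lists for this contrast. Proinflammatory cytokines and chemokines had a median difference of 0.42 on the log2 scale (adjusted p = 0.00102), NF-kappaB targets and feedback regulators 0.20 (0.00363), interferon-stimulated genes 0.87 (0.00469) and antigen presentation genes 0.25 (0.0286). Within replicates 1 and 2 the medians were 0.54 and 0.08 for interferon-stimulated genes and 0.21 and 0.19 for antigen presentation genes. For interferon-stimulated genes both values lie below 0.87, and the WT_rest libraries lay apart, at median log2 CPM of 6.66 and 4.86. Cell cycle and DNA replication genes had a median difference of -0.25 (adjusted p = 0.00363), which is a deeper fall in KO. Mitochondrially encoded genes had 0.24 (adjusted p = 0.00722), liver X receptor targets 0.15 (0.0235), heat shock genes 0.12 (0.0431), cytosolic ribosomal proteins 0.07 (0.0198) and lysosome and autophagy genes 0.07 (0.0229). With an estimated correlation the adjusted p was 0.774 to 0.791 for these 10 lists, and no member gene passed in edgeR (84 of all genes at an unadjusted p under 0.05, 0 in DESeq2).

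Libraries with the same replicate number deviated from their group means together in all 4 groups. Xist, which only the inactive X chromosome transcribes, had a total of 26839 counts in replicate 1 and 1 in replicate 2, or 0.00373%, and Ddx3y, Eif2s3y, Kdm5d and Uty were counted in each replicate 2 library and had 0 counts in replicate 1. The labels call all samples female, but the 4 Y-linked genes had 521 to 3385 counts per replicate 2 library, which argues against that label for replicate 2. These libraries look like those of male animals. Genes of the sex chromosomes alone are argued against, since the lowest of the 6 correlations was 0.206 over autosomal genes. A preparation or sequencing batch cannot be told apart from 2 different sets of animals, since both share the replicate number, and sex stays open as well, while the share of autosomal genes decides nothing, at 96% of the 2877 genes called for the replicate number against 96.9% of all tested genes.

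Interferon-stimulated genes lay higher in WT than in KO within replicate 1, as their median log2 CPM at rest was 6.66 in WT_rest replicate 1 and 4.86 to 5.12 in the other 3 libraries, and after LPS it was 7.38 in WT_LPS replicate 1, 7.42 in WT_LPS replicate 2, 6.49 in KO_LPS replicate 1 and 8.24 in KO_LPS replicate 2. Whether the MYC deletion lowers these genes cannot be decided, since the 2 replicates differ in direction. Within replicate 2 the list lay higher in KO, by medians of at least 0.488 on the log2 scale at rest and after LPS (lower quartiles of the members 0.261 and 0.484). Each difference compares 1 KO with 1 WT library, and quartiles over members do not measure the spread between libraries. The 2 libraries of WT_rest (6.66 and 4.86) and of KO_LPS (6.49 and 8.24) lay further apart than that, while those of KO_rest and WT_LPS lay close. A single aberrant library behind both differences is argued against, since WT exceeded KO by at least 1.091 in both conditions, which share no library, but a high WT_rest replicate 1 and a low KO_LPS replicate 1 of separate origin stay open. LPS with the effect measured at 3 h in the unstimulated WT replicate 1 culture is argued against, since within replicates LPS moved NF-kappaB targets by medians of 3.74 to 4.25 and interferon-stimulated genes by 0.22 to 2.66, while NF-kappaB targets of this library differed from the other 3 unstimulated libraries by -0.218, 0.049 and 0.359 (highest upper quartile 0.611) and interferon-stimulated genes by 1.363 to 1.763. The proinflammatory list differed by medians of 0, 0.121 and 0.433, although its share of counts was the highest at rest (0.148% against 0.0608% to 0.106%, and 2.71% to 6.13% after LPS), and an LPS exposure of another length and a difference between the animals or cultures were not tested and stay open.

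The neutrophil and monocyte lists and 4 class II genes (H2-Aa, H2-Ab1, H2-Eb1 and Cd74) lay higher in KO. These 4 genes were chosen after the data were seen and were not tested as a list. At rest the antigen presentation list lay lower in KO within replicate 1 and higher within replicate 2. S100a8, S100a9, Ngp, Ltf and Camp, which neutrophils make in large amounts, were higher in KO in 20 of 20 within-replicate differences, which may reflect more RNA of neutrophils or higher expression in the macrophages. These cannot be told apart, since the 5 differences ranged over 0.52, 0.92 and 0.95 on the log2 scale in 3 of the 4 pairs, within the range set for a constant share of neutrophils, and over 1.81 in the rest pair of replicate 2, past that range but under the bound set to exclude it. For these 4 class II genes, 2.02 to 2.42 higher at rest, dendritic cell markers had a median of 0.555, and only 4 of 12 markers exceeded 2 CPM, too few to decide on RNA of dendritic cells.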

How the results depend on the processing

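The count variations of the fit with the block and the omission of both WT replicate 1 libraries were chosen after the data were seen, and the other alternatives before. Of 235 results for named genes, 235 kept their direction and side of the threshold with RLE factors, 233 without a filter, 179 with DESeq2 (56 passed in addition), 227 with limma-voom and 139 with the block (92 passed in addition). With only the groups compared 15 of 225 no longer passed and 2 reversed, and without both WT replicate 1 libraries 15 of 235 and 10. With each library left out in turn, 96 of 1880 values no longer passed and 34 reversed. Of the 61 named genes that passed after LPS in WT, 38 passed with each library left out and 5 in at most 3 of these 8 fits (Irf2, Odc1, Paox, Polr3g and Ppat), and in KO 35 of 46 and 2 (Hspa5 and Tap2). The number of genes called after LPS in WT was 4677 with the block, 1085 with only the groups compared, 785 to 1927 with 1 library left out and 983 without both WT replicate 1 libraries. With the block it was 1922 to 4720 with 1 library left out and 3107 without both. In KO it was 6159 with the block, 1224 to 3357 with 1 library left out, and with the block 2999 to 6206. KO against WT at rest gave 120 genes in DESeq2 and 167 in edgeR with the block. The 167 became 408 without a filter, 665 in DESeq2, 0 to 178 with 1 library left out and 0 without both WT replicate 1 libraries. KO against WT after LPS gave 221 in DESeq2 and 603 with the block. The 603 became 939 without a filter, 1367 in DESeq2, 0 to 472 with 1 library left out and 0 without both. With 1 library left out the spread rests on fewer degrees of freedom, and a lone library is assumed to vary like the other groups. Some counts rose all the same, to 178, 4720 and 6206. Leaving out all replicate 2 libraries would leave 1 per group and was not run. Of the 10, 11, 18, 16 and 10 lists called by camera in the 5 contrasts, 0, 0, 0, 0 and 0 passed with an estimated correlation. NF-kappaB targets after LPS in WT, of which 28 of 30 rose, were among those that did not (adjusted p = 0.35). A failure with an estimated correlation therefore does not show that a list was unchanged. The preset correlation of 0.01 has a limit too. For LPS in WT without the block, estimates ran from -0.072 (MYC network) to 0.85 (interferon-stimulated genes), with 0.819 for ribosomal proteins. Where genes of a list move together, the camera p with the preset correlation can be far too small. Fry called 3, 5, 5, 6 and 0 lists. For the other tools, the filter, the block and the list tests the cause was not tested. Reversals were in values near 0 or in genes with a wide spread. Those of Irf7, Arg1 and Nos2 at rest came only in fits without WT_rest replicate 1, and that of Il6 after LPS only without KO_LPS replicate 2. Why these libraries differ was not tested, nor was the cause of the other reversals. Irf4 after LPS in WT was -0.096 with limma-voom, -0.009 with limma-trend, -0.026 with the block, -0.686 to 0.676 with 1 library left out and -0.654 without both WT replicate 1 libraries. Without both, the difference of the Myc responses was -0.131. With 1 library left out, Myc ranged from -1.711 to 0.073 after LPS in WT, from -1.011 to 0.266 in KO and from -0.578 to 1.341 for the difference. For KO against WT at rest, only the groups compared gave -0.02 for Hif1a and -0.022 for Hk2, and Hk2 was -0.007 with limma-voom and -0.05 with the block. Without both WT replicate 1 libraries, Nos2 was 0.291, Il10 0.191, Arg1 0.059 and Irf7 0.864. With 1 library left out the ranges were -0.11 to 0.113 for Hif1a, -0.231 to 0.208 for Hk2, -0.342 to 0.411 for Slc2a1, -0.376 to 1.064 for Il12b, -0.65 to 0.266 for Nos2, -0.776 to 0.242 for Il10, -2.634 to 0.027 for Arg1 and -3.271 to 0.837 for Irf7. For KO against WT after LPS, limma-voom, limma-trend, the block and the omission of both libraries gave -0.123, -0.129, -0.028 and -0.082 for Hk2 and -0.093, -0.099, -0.031 and -0.554 for Il10. That omission gave -0.072 for Il12b and 0.125 for Irf7. With 1 library left out the ranges were -0.983 to 0.742 for Hk2, -0.583 to 3.322 for Il6, -0.173 to 2.188 for Il12b, -1.146 to 0.795 for Nos2, -1.56 to 1.28 for Il10 and -2.516 to 0.161 for Irf7. With 3 counts as the floor, depth limits genes under 0.137 to 0.227 CPM per library.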

Other observations

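The tests in this part were chosen after the result was seen. Whether genes that LPS induces most lie higher in KO after LPS was tested across replicates and stays open. The 200 genes most induced by LPS in WT replicate 1 had a median log2 value of 0.475 for KO against WT after LPS within replicate 2, where 175 were higher, and the 200 chosen in WT replicate 2 had 0.485 within replicate 1, where 154 were higher. Each median compares 1 KO with 1 WT library, and induced genes move together, so random lists of genes give no valid threshold. The NF-kappaB and proinflammatory lists did not pass after LPS in camera with an estimated correlation (adjusted p = 0.254 for each). That failure decides nothing, since this test passed 0 lists in every contrast. It did not pass even NF-kappaB targets after LPS in WT, of which 28 of 30 rose (adjusted p = 0.35). Markers of other cells lay higher in KO after LPS by more, at list medians of 1.78 for neutrophils, 1.79 for monocytes and 1.34 for dendritic cells. At rest the medians of the induced genes were 0.177 and 0.049. Both replicates include the same genotypes, so the test does not separate a Myc effect from another difference between the KO and WT animals.

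DNA linked to the deleted Myc allele is a candidate explanation for some genes called between KO and WT after LPS with the block. Within 20 Mb of Myc, 18 of 218 tested genes other than Myc were called, 8.26% against 4.28% elsewhere, an odds ratio of 2.01 (95% interval 1.16 to 3.29, Fisher exact p = 0.0104, adjusted p = 0.0208). Around Lyz2, the Cre locus that both genotypes share, 7.14% were called, an odds ratio of 1.7 (0.827 to 3.16, Fisher exact p = 0.107). The 2 intervals overlap, so the surroundings of Myc are not shown to differ from those of Lyz2. The calls counted here fell to 0 without either WT_LPS library or without KO_LPS replicate 2. Neighbours of a gene are often regulated together, so this remains a hypothesis.

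Lyz2 was at 8.22 to 34.9 CPM and Lyz1 at 17.3 to 65.3 CPM over the 8 libraries. The 2 genes are paralogs, so reads that match both are a limit on either value. Lyz2 is an abundant transcript of macrophages, so these levels are low, and the reason was not tested.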
